A study of Mus musculus with 10 samples.

How the data were processed

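RNA from 5 GFP+ and 5 GFP- samples of conventional CD4+ T cells was measured on 10 Agilent mouse arrays with Cy3 labelling after global PCR amplification, per the labels. The deposited scanner files give each spot's intensity, which the authors' scans passed through Agilent Feature Extraction 10.7.3.1, with background subtraction and spatial detrending. The deposited value table is on a log2 scale and appears quantile-normalized between arrays, since its columns have nearly equal medians (3.21 to 3.22, with 0 to 160 missing values) and order the probes as the scanner intensities do (Spearman correlation across probes 0.9999 to 1.0). The scanner intensities were used and the table served as an alternative. Probe coordinates are on mm9, per the file headers. The labels do not say whether replicates came from separate mice, nor how GFP gates were set.

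Of 62976 spots per array, 3671 were controls, and the rest gave 55681 probes after averaging repeated spots. No spot was saturated. Probes were named by RefSeq accession (27235), symbol (3581) or synonym (565), and 24300 kept the name in the files. Well above background were 10164 probes on all arrays, 28116 on 1 to 9 arrays and 17401 on none. Genes detected per array averaged 15838 ± 1459 (SD, n = 5) in GFP+ and 17144 ± 1005 (SD, n = 5) in GFP- samples.

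Levels are log2 intensities minus each array's 75th percentile over the 10164 probes well above background on all arrays. The scaling planned before the data were examined used the 75th percentile over all probes. It was replaced before any group test, and the reason given was that under 50% of spots lay above background on every array. Such a share does not by itself place a 75th percentile among undetected spots. The planned percentile varied from 4.69 in GFP+ replicate 4 to 8.18 in GFP+ replicate 1 on the log2 scale. The percentile used varied from 12.25 in GFP+ replicate 4 to 13.62 in GFP- replicate 2. The planned scaling is reported as an alternative. It moved the median difference of all genes to 0.22, median scaling to -0.14, quantile normalization and the value table to 0.12 and normexp to 0.11, against 0.01 with the scaling used.

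Each gene was represented by its brightest probe among those well above background on at least 4 of 10 arrays, which left 17798 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. Where a gene lay above background on no array of a group, its fold is a lower bound computed against the lowest signal well above background on each array of that group. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry (directional and mixed) as alternatives. Of 26 lists fixed before the data were examined, 20 for T cell states and pathways and 6 for other cell types, 25 had the 5 tested members required.

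Named genes followed a rule written in advance. It takes Il2, the called genes with separated groups, a fill to 10 per direction by smallest p, and up to 4 members of each list by smallest p, leaving out features without a gene symbol. A gene that this rule names is not reported in the text. The depth of 4 members for called lists and 2 for others was set after p values were seen. The kappa light chain probe falls outside the rule and was named after its value was seen, as were the immunoglobulin sets and further plasma cell and neutrophil genes. Single levels per array were compared by exact permutation over all assignments of 5 arrays.

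On simulated data with the spread of these arrays (17784 genes), the GFP+ against GFP- fit called 0% of 50 genes changed by a log2 of 1, 16% at 2, 54% at 4 and 54% at 8. It also called 6 of 17584 unchanged genes. A log2 change of 1 was therefore not recovered for any of the 50 simulated genes that carried it. The simulation drew normal noise with each gene's residual SD and did not model drops to background on single arrays.

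Alternatives were the planned, median and quantile scalings, normexp background correction (offset 50), the value table, no probe filter or detection on all 10 arrays, and the mean of a gene's probes. Others were eBayes with trend and robust, array weights, replicate number or slide as a block, each slide alone, each array and each replicate number left out, and other thresholds. Array brightness as a covariate was added after the data were seen. Replicate numbers were not used as pairs, since the study's design names no covariate, and the fit with them as a block was planned as an alternative. In a check made with the main fit, correlations between samples of equal number, after group means were removed, ran from -0.079 to 0.07. The best partner shared the number for 2 of 5. With the wide spread of these arrays, this check does not rule out that equal numbers are pairs. Slide 1 held numbers 1 and 3, slide 2 numbers 2 and 4, and slide 3 number 5. GFP+ and GFP- arrays lay in different columns of the slides, so position and group cannot be told apart.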

Results

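Conventional CD4+ T cells from the spleen and lymph nodes of untreated adult female mice that carry an IL-2 GFP reporter were profiled as 5 GFP+ and 5 GFP- samples, each on its own single-colour microarray, with GFP- as the study's control. The comparison asks how the transcripts of cells that report Il2 expression differ from those of cells that do not. Each array held 62976 spots, of which 29.9% (GFP+ replicate 4) to 44.9% (GFP- replicate 5) lay well above background. That share was 36.9% ± 4.49 (SD, n = 5) in GFP+ and 40.7% ± 2.82 (SD, n = 5) in GFP- samples, with an exact two-sided permutation p = 0.159. The number of arrays limits the precision of every value. Levels are log2 signals relative to the 75th percentile of each array's well detected probes, and differences are GFP+ minus GFP-.

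The values of the Il2 transcript itself overlapped between the groups. Its probe (mm9, chromosome 3, 37020012 to 37020071) lay well above background on 2 of 5 GFP+ and 2 of 5 GFP- arrays. The Il2 level was -6.64 ± 4.29 (SD, n = 5) in GFP+ and -7.44 ± 4.18 (SD, n = 5) in GFP- samples. The Il2 difference of 0.79 had a standard error of 2.49 (limma, adjusted p = 0.962). It was 4.61 on slide 1, -6.71 on slide 2 and 8.17 on slide 3, where the last slide held 1 array of each group and gave no test. No probe on the array was named GFP, so the reporter's own transcript was not measured.

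Coq10a, which encodes a mitochondrial coenzyme Q-binding protein, was lower in GFP+ cells. Abraxas1, which encodes a scaffold of the BRCA1-A DNA repair complex, and a probe for an immunoglobulin kappa light chain mRNA were lower as well. Coq10a (mm9, chromosome 10, 127800356 to 127800415) lay at -10.45 ± 0.39 (SD, n = 5) in GFP+ and -0.93 ± 0.96 (SD, n = 5) in GFP- samples, above background on 0 of 5 and 5 of 5 arrays. The Coq10a signal was at least 181-fold lower in GFP+ cells (log2 difference -9.52, standard error 0.48, adjusted p = 9.76e-05). Abraxas1 (mm9, chromosome 5, 101234918 to 101234977) lay at -10.31 ± 0.32 (SD, n = 5) against -4.24 ± 1.41 (SD, n = 5), also above background on 0 of 5 against 5 of 5 arrays. The Abraxas1 signal was at least 18.2-fold lower (log2 difference -6.07, standard error 0.64, adjusted p = 0.0237), and its adjusted p was 0.072 with each array scaled on all its probes, 0.112 with slide as a block and 0.780 with replicate number as a block. With normexp background correction the Coq10a difference was -5.98 and that of Abraxas1 -2.73 (adjusted p = 0.309), both short of the bounds given, which hold for the scanner software's own background subtraction. The kappa probe (mm9, chromosome 6, 69581780 to 69581839) lay at -8.81 ± 0.98 (SD, n = 5) against -1.40 ± 0.97 (SD, n = 5), a log2 difference of -7.41 with a standard error of 0.61 (adjusted p = 0.00423), and was above background on 2 of 5 against 5 of 5 arrays. With slide or with replicate number as a block, only Coq10a of these 3 kept its call.

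These 3 were the only calls among 17798 genes tested with limma, and 0 genes were higher at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 646 higher and 518 lower genes, against 890 expected by chance in both directions together. The smallest adjusted p of a higher gene was 0.156. With each array scaled on all its probes, as first planned, 0 genes were called higher and 2 lower, and 355 and 517 passed the unadjusted threshold. All GFP+ values exceeded all GFP- values for 292 genes and lay below them for 116, where chance separates 0.79% of genes, or 141, in both directions together. The typical spread within groups was wide, with a median residual SD of 1.42 on the log2 scale.

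Among higher values, none of which passed the adjusted threshold, Ubn1 had a log2 difference of 3.12 and Elk3 of 2.87, each with all GFP+ values above all GFP- values. Gdi2 had a difference of 1.30, a probe named for the mitochondrial gene ND3 of 1.24, Ino80e of 3.99 (-0.82 through another probe with no filter on dim probes), Zic4 of 1.37 and the pseudogene Vmn2r-ps54 of 1.21. Igsf10 lay above background on 5 of 5 GFP+ and 0 of 5 GFP- arrays with a signal at least 3.09-fold higher. Nectin2 and Gpc3 each lay above background on 4 GFP+ and 0 GFP- arrays, with signals at least 2.87-fold and 2.40-fold higher. These bounds too hold for the scanner software's background subtraction, since with normexp the log2 differences were 0.80 for Igsf10, 0.79 for Nectin2 and 0.72 for Gpc3. With the mean of its probes, Elk3 had a difference of 1.29.

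Among lower values that did not pass, the neutrophil granule gene Ngp had a log2 difference of -8.17 and the folate enzyme gene Mthfd1l of -8.04. Arl5c had a difference of -6.35. Through any of their probes, Mthfd1l and Arl5c each lay above background on 3 GFP+ arrays. The sterol regulation gene Insig1 differed by -6.23, Treml2 by -4.84, the VIP receptor gene Vipr1 by -4.67 and Fam174c by -4.42. Their adjusted p values ran from 0.156 for Fam174c to 0.247 for Vipr1. Without GFP+ replicate 1, Mthfd1l had an adjusted p of 3.60e-04, and without GFP+ replicate 5, Ngp had 1.40e-04, Insig1 0.0134 and Fam174c 0.044. Without GFP- replicate 3, Arl5c had 0.0022. For Ngp and Mthfd1l the array left out was the GFP+ array that stood high against the others. For Insig1 (-4.94) and Fam174c (-4.00) the array left out also had the highest GFP+ value. For Arl5c it had the lowest GFP- value (-7.76). Each of these gains thus came from leaving out the array of its group that lay nearest to the other group. Over 15 omissions of an array or number, the highest adjusted p (limma) was 0.707 for Mthfd1l and 0.675 for Ngp and Insig1. It was 0.523 for Fam174c and 0.384 for Arl5c. With normexp the difference was -3.19 for Arl5c, -2.11 for Vipr1, -5.33 for Ngp and -4.06 for Insig1, and with the mean of its probes it was -4.97 for Mthfd1l.

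**Figure D1:**
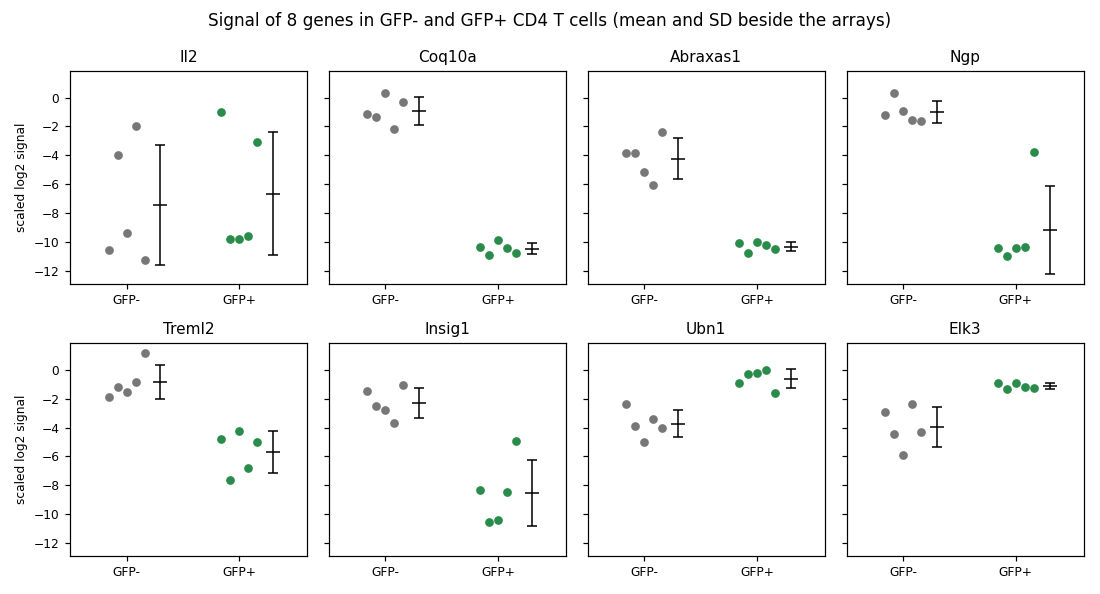
Each point is the log2 level of 1 array, relative to the 75th percentile of its well detected probes, for Il2, Coq10a, Abraxas1, Ngp, Treml2, Insig1, Ubn1 and Elk3 in the 5 GFP+ and 5 GFP- samples, with group means and SD. Coq10a averages -10.45 in GFP+ and -0.93 in GFP- samples, whereas the Il2 values of the groups overlap.

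Genes of naive and resting T cells were lower in GFP+ cells as a group by camera at its preset correlation, though not with an estimated one. The TREM-like receptor gene Treml2 (-4.84), Als2cl (-1.28), Igfbp4 (-4.78) and the lymph node homing receptor gene Ccr7 (-3.52) had the smallest p values on this list. Of 30 naive genes tested, 22 had negative differences, with a median of -0.87 (camera, adjusted p = 0.0013; adjusted p = 0.393 with an estimated correlation). No member passed over all genes by limma, 5 were lower at an unadjusted p under 0.05, and 1, Treml2, was lower when adjusted over the list alone. The naive list kept its call when any 1 array was left out, but its median was -0.32 without GFP+ replicate 4 and -0.28 without both arrays of that number. It was -0.46 with array brightness as a covariate (adjusted p = 0.0023) and -0.47 among genes detected on all 10 arrays (adjusted p = 0.00389).

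Oxidative phosphorylation and cholesterol synthesis genes were also lower by the preset-correlation test alone. Cox8a (-4.45), Ndufs7 (-2.33), Cyc1 (-4.24) and Ndufs8 (-4.84) led the oxidative phosphorylation list, and Insig1 (-6.23), Sqle (-4.57), Ebp (-4.39) and the regulator gene Srebf2 (-3.86) the cholesterol list. The oxidative phosphorylation median was -0.56, with 43 of 59 genes negative (camera, adjusted p = 0.0324; adjusted p = 0.863 with an estimated correlation). Of these genes 0 passed by limma over all genes or adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05. The cholesterol median was -1.34, with 14 of 20 genes negative (camera, adjusted p = 0.038; adjusted p = 0.393 with an estimated correlation). Of its genes 0 passed by limma over all genes, 4 were lower at an unadjusted p under 0.05, and 1, Insig1, was lower adjusted over the list alone. With array brightness as a covariate the medians were -0.30 for oxidative phosphorylation (adjusted p = 0.198) and -0.78 for cholesterol (adjusted p = 0.0866). Among genes detected on all 10 arrays they were -0.13 (adjusted p = 0.515) and 0.22 (adjusted p = 0.817). With array weights the oxidative phosphorylation median was -0.26 (camera, adjusted p = 0.171). Without GFP+ replicate 3, GFP+ replicate 4 or GFP- replicate 3, the oxidative phosphorylation list had adjusted p values of 0.115, 0.339 and 0.159 and the cholesterol list 0.172, 0.0655 and 0.159. Without GFP- replicate 2 the oxidative phosphorylation list had 0.225, and without GFP+ replicate 1 the cholesterol list had 0.0556. The oxidative phosphorylation median was -0.21 without GFP+ replicate 4, -0.99 without GFP+ replicate 5 and -0.90 without GFP- replicate 5, and the cholesterol median was -0.64 without GFP+ replicate 4. The directional fry test called 0 lists, with 2, naive and cholesterol, at an unadjusted p under 0.05.

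Gene lists of T cell activation did not pass the camera threshold. Cytokine and chemokine genes of activated CD4 T cells had a median of 0.50 (adjusted p = 0.801), with Tnfsf11, which encodes RANKL, at 5.81 and Mif at -4.32. Immediate-early genes of T cell receptor signalling had a median of -0.49 (adjusted p = 0.599), with Spry2 at 0.99 and Egr2 at -2.09. Co-stimulatory and inhibitory receptor genes had a median of 0.35 (adjusted p = 0.874), with Tnfrsf18 at -3.40 and Tox at 3.88. IL-2 and STAT5 response genes had a median of -0.68 (adjusted p = 0.404), with Stat5a at -4.35. Anergy genes had a median of 0.23 (adjusted p = 0.900), with the surface receptor gene Izumo1r at 4.91. Effector and memory genes had a median of 0.04 and a mean of -0.09 (adjusted p = 0.898), with Anxa1 at -3.90 and Nkg7 at -2.49.

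T helper subset genes likewise stayed above the threshold. T follicular helper genes had a median of 0.46 (camera, adjusted p = 0.404), with Pou2af1 at 5.12. Regulatory T cell genes had a median of 0.33 (adjusted p = 0.874), Th1 genes 0.31 (adjusted p = 0.972) with Cxcr3 at 4.99, and Th2 genes -0.87 (adjusted p = 0.599) with Il4ra at -0.87 and Stat6 at -2.34. Th17 genes had a median of -0.05 (adjusted p = 0.972), or 0.31 with quantile normalization (adjusted p = 0.891), with Tmem176b at 2.37 and Maf at 0.65. T cell identity genes had a median of -0.24 (adjusted p = 0.626), with Cd6 at 1.09 and Trat1 at -2.40.

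The remaining programmes gave no call. Cell cycle genes had a median of -0.18 but a mean of 0.26 (camera, adjusted p = 0.626), with Spc25 at 1.49 and Cdca8 at 2.19. Interferon response genes had a median of -0.86 (adjusted p = 0.626), with Ifit2 at -5.63 and Irf1 at -3.07. Glycolysis genes had a median of 0.26 (adjusted p = 0.626), with Slc2a1 at -3.31 and Bpgm at 1.29. Cytosolic ribosomal protein genes had a median of 0.14 (adjusted p = 0.404), or -0.076 with quantile normalization (adjusted p = 0.0876), with Rps14 at -0.78 and Rpl36 at -0.76. That ribosomal list passed without GFP+ replicate 1 (adjusted p = 0.0298) and without GFP- replicate 4 (adjusted p = 0.0478) at the preset correlation, whereas with all arrays it had adjusted p = 0.944 with an estimated correlation. Heat shock and stress genes had a median of 0.26 (adjusted p = 0.626), with Bag3 at 4.85 and Ddit4 at -3.61.

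Markers of other cell types gave no list-wide call. Myeloid and dendritic cell markers had a median of -0.40 (camera, adjusted p = 0.404), and Ngp alone was lower when adjusted over the list alone, with S100a8 at -6.57. B cell markers had a median of -0.02 and a mean of 0.04 (adjusted p = 0.972), or a median of 0.35 with quantile normalization (adjusted p = 0.789), with the antibody joining chain gene Jchain at -1.75 and Ebf1 at 1.96. NK and NKT cell markers had a median of 0.19 while camera ranked them below the other genes (adjusted p = 0.972), with Klrb1a at 3.60. Erythroid and platelet markers had a median of -1.42 (adjusted p = 0.469), with Epb42 at 1.32 and Hbb-b2 at -3.32. Stroma and endothelium markers had a median of -0.12 and a mean of 0.01 (adjusted p = 0.874), with Ccl19 at 1.23 and Col1a2 at 0.41. Of the CD8 and gamma-delta T cell markers only Crtam (1.75) and Eomes (1.52) were tested, too few for camera. Across the 22 lists that did not pass, limma called 0 genes over all genes and 1, Ngp, adjusted over the list alone.

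Immunoglobulin kappa probes had mostly negative differences. Of 63 kappa probes tested, 57 had negative differences, with a median of -3.04. At an unadjusted p under 0.05, 27 kappa probes were lower and 0 higher, and limma called 1. All GFP+ values lay below all GFP- values for 19 of them, where chance separates 0.79% in both directions together. The kappa probes of smallest p (limma over probes, unadjusted p up to 6.98e-04) all lay on chromosome 6 from 68757412 to 69850477 (mm9). Most of these were named for variable segments of families 4 and 5. Whether probes of related segments share signal was not tested, so these counts need not be of independent results or hold for all kappa segments alike. The mean kappa level was -6.45 ± 0.69 (SD, n = 5) in GFP+ and -3.26 ± 0.44 (SD, n = 5) in GFP- samples. Its difference of -3.19 had an exact two-sided permutation p = 0.00794, the smallest that 5 against 5 arrays can give, and 0.0238 after Benjamini-Hochberg adjustment over 3 chain types. Heavy chain probes differed by -1.59 in mean level (exact permutation p = 0.0635, adjusted 0.0952) and lambda chain probes by -2.64 (exact permutation p = 0.135, adjusted 0.135). The kappa set was chosen after its values were seen. Its probe for the kappa constant region lay at 1.71 ± 0.67 (SD, n = 5) in GFP+ and 2.88 ± 0.20 (SD, n = 5) in GFP- samples. That probe was above background on 5 of 5 arrays in each group and differed by -1.17 (limma over probes, adjusted p = 0.625). The mean over probes therefore does not give the difference of kappa RNA as a whole.

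**Figure D2:**
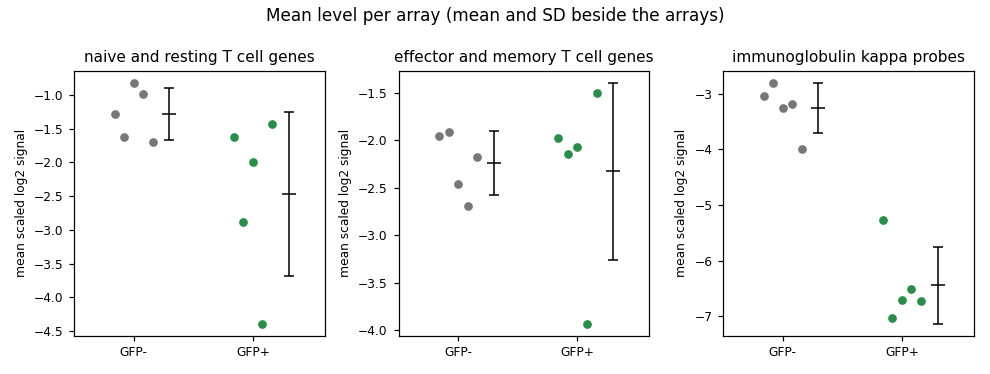
Each point is 1 array's mean log2 level of the naive and resting T cell list, the effector and memory list, and the immunoglobulin kappa probes, for the 5 GFP+ and 5 GFP- samples, with group means and SD. Kappa levels average -6.45 in GFP+ and -3.26 in GFP- samples.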

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

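The check in this part was not chosen after its result was seen. The genes checked, apart from Il2, were picked by their values on these same arrays, so the count given by chance is a rough guide. Within groups of 5, single arrays lay far from the other 4 in 11 of 144 checks of named genes and array measures, where chance gives about 7. Among GFP+ samples, replicate 5 stood high for the granule gene Ngp (-3.78, others -10.95 to -10.38) and the sterol isomerase gene Ebp (-3.73, others -10.94 to -10.44). Replicate 1 stood high for Mthfd1l (-2.91, others -10.54 to -9.47) and Ebf1 (-4.1, others -8.17 to -7.5). Replicate 4 was low for Cxcr3 (-10.4, others -1.74 to 0.73) and replicate 2 for Stat6 (-10.89, others -3.32 to -0.62).

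Among GFP- samples, replicate 1 stood high for Tnfsf11 (-5.51, others -11.49 to -10.79) and replicate 5 for Klrb1a (-3.55, others -11.39 to -10.81). Replicate 2 was low for Stat5a (-9.78, others -4.01 to -2.11) and Maf (-2.7, others -1.02 to -0.34), and replicate 4 for Zic4 (-7.9, others -7.34 to -7.14). No array held over 2 of the 11 values. No biological or technical explanation was tested for them.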

How the results depend on the processing

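Array brightness as a covariate and all alternatives of the kappa level and of the naive list's mean level were chosen after the results were seen. Of 2873 comparisons with the reported values, 2681 kept direction and side of the threshold or, for counts, stayed within 1.5 times. Of the rest, 43 lost a call, 11 gained one, 34 counts moved further and 104 changed direction. The cause was not tested. Most genes and lists compared had no call to lose, so the share kept does not measure robustness. The count of lower genes, 3 as reported, was 0 with detection on all 10 arrays (198 at an unadjusted p under 0.05; limma could not test Coq10a there), 0 within slide 1 (566) and within slide 2 (1144), where fewer arrays are tested, and 1 with replicate or slide as a block. Lists past the threshold, 3 as reported, numbered 1 with median scaling, detection on all 10 arrays, probe means, brightness as a covariate, slide 1 and slide 2, and 0 with an estimated correlation or fry. With 1 array or number left out, higher genes ranged from 0 to 8, lower genes from 2 to 22, lists from 1 to 4 and Il2 from -1.41 to 2.89. The 8 higher genes came without number 4, whose GFP+ array had the fewest detected genes (13540). The 22 lower genes came without number 5. Lower genes numbered 11 without GFP+ replicate 1, 14 without GFP+ replicate 5, 7 without GFP+ replicate 2, GFP- replicate 3 or GFP- replicate 5, and 6 without GFP- replicate 4. Higher genes numbered 1 without GFP+ replicate 2 or GFP+ replicate 4, and 2 without GFP- replicate 4. Il2 was negative without GFP+ replicate 1 (-0.63), GFP+ replicate 5 (-0.10) or GFP- replicate 5 (-0.16), and -6.71 within slide 2. Coq10a kept its call under all 12 alternatives on the whole series that tested it (adjusted p 3.73e-05 to 0.0322) and lost it within slides 1 (-9.71) and 2 (-8.91). Abraxas1 ranged from 0.00689 to 0.780 in adjusted p, losing its call without GFP+ replicate 3 (0.0669), GFP+ replicate 4 (0.061), GFP- replicate 1 (0.101) or GFP- replicate 2 (0.0674). The naive list kept its call under 13 alternatives on the whole series (adjusted p 2.58e-07 to 0.00389), but not with an estimated correlation or fry, nor within slides 1 (-0.30) and 2 (-1.80). The cholesterol median was 0.22 with detection on all 10 arrays. The kappa level was -2.27 with normexp and -3.49 to -3.04 with 1 array left out.

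For lists the direction is that of camera, which sets a list against the other genes. The printed median can therefore keep the sign of the reported one. Changes of direction, given as medians for lists, were as follows. On all probes they were effector 0.26, Th17 0.16 and B cell 0.20; with median scaling Th17 -0.20, B cell -0.17 and NK 0.034. Quantile normalization gave effector 0.19, Th1 0.38, Th17 0.31, ribosomal -0.076 and B cell 0.35, and the value table effector 0.20, Th1 0.38, Th17 0.31, ribosomal -0.086 and B cell 0.34. Normexp gave Th1 0.17. No filter gave Ino80e -0.82, effector 0.17, regulatory 0.50, Th1 0.31, Th17 0.13, anergy 0.27, cell cycle 0.46, glycolysis 0.68, ribosomal 0.14 and heat shock 0.32. Detection on all 10 arrays gave cytokines -0.25, Th1 0.21, IL-2 response 0.48 and interferon 0.30, and probe means B cell 0.11. Array weights gave Th17 0.12, B cell 0.16, NK 0.22 and stroma -0.18, the replicate block Th17 -0.050, and brightness as a covariate Th17 0.093, ribosomal 0.056 and B cell 0.44. Slide 1 gave Egr2 0.046, Stat6 0.044, Cyc1 0.038, Eomes -0.84, effector 0.19, Th1 0.031, glycolysis 0.064, ribosomal 0.026, heat shock -0.19 and NK 0.14. Slide 2 gave Crtam -1.87, cytokines -0.45, co-stimulatory -0.27, regulatory -0.27, Th1 0.037, Th2 -0.12 and anergy -1.20, and slide 3, untested, oxidative phosphorylation 0.77. With 1 array or number left out the ranges were B cell -0.32 to 0.42, ribosomal 0.025 to 0.19, effector -0.041 to 0.38, Eomes -0.32 to 3.88, glycolysis 0.14 to 0.39, interferon -1.06 to 0.33, stroma -0.12 to 0.26, NK -0.51 to 0.77, regulatory -0.10 to 0.63, anergy -0.24 to 0.58, T cell identity -0.34 to 0.045, Th1 -0.34 to 0.46 and Th17 -0.48 to 0.29. Of 55681 probes, 28116 were detected on some arrays only. Whether signal near background underlies these changes was not tested. With detection on all 10 arrays, 4 of 50 results still changed direction.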

Other observations

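In this part, the tests on kappa, naive and neutrophil genes and on genes detected in a single group were chosen after the results were seen, and the regroupings for called genes and lists were planned. Chance cannot be excluded for the number of called genes, which says nothing of the strength of any 1 gene such as Coq10a, since 51 of 100 splits of the 10 arrays called as many, with 3 for the real split and 51 for the highest other. That highest split parted the 5 brightest arrays (lowest 7.62, others at most 7.09, log2 75th percentile of all probes). The splits with the next most calls (17, 17, 15 and 14) did not part the arrays fully by brightness. Each still held the brightest arrays together, GFP+ replicates 1 (8.18) and 5 (7.98) and GFP- replicate 1 (7.92). In each, the dimmest array, GFP+ replicate 4 (4.69), lay on the other side. Whether brightness underlies the calls of these splits was not tested. Chance cannot be excluded for the lists either, since 11 of 100 splits had at least 3 past the threshold and the highest other had 5. All these splits ignored slide, whereas each slide holds both real groups in equal number. No split within slides was run. At an unadjusted p under 0.05 by limma, a count not planned as a test of the splits, the real split held 1164 genes. Most other splits held fewer, and the highest held 1312. Detection on all arrays of a group and none of the other held for 3 genes in GFP+ (Igsf10, Mid2 and Slc10a4) and 17 in GFP-, among them Coq10a, Abraxas1 and Vangl2, and 9 of 126 splits gave as many as these 20, with 38 in the highest other.

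The kappa level was lower in GFP+ samples with an exact permutation p = 0.00794, the smallest possible, but the set was noticed on these same arrays, so this p cannot argue against chance. Fewer detected probes on GFP+ arrays do not account for it, since the difference was -3.17 (standard error 0.45) with the share of detected spots as a covariate and -3.19 without. RNA of antibody-secreting cells in the GFP- samples may be a source, and 2 tests of this disagreed. The first, on 13 plasma cell genes without Jchain, gave a median of -0.05 with 7 of 13 negative (from Txndc5 at -3.99 to Pou2af1 at 5.12), which met the bound set against this source; the second, chosen after that outcome with its values already seen, gave -1.70 over heavy and lambda probes, 29 of 35 negative. The source stays open, since all 13 genes, such as Xbp1, Prdm1 and Irf4, were above background on a GFP+ array and 4 are on fixed T cell lists, so that their baseline can hide a small share, since Jchain (-0.90 in GFP- samples, difference -1.75) did not pass, and since the labels give no gate on B lineage cells; no difference within the T cells themselves was tested as an explanation.

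The lower naive and resting T cell genes may partly follow array detection. Their mean level differed by -1.19 (standard error 0.57; exact permutation p = 0.0397, adjusted 0.0595 over 3 scores) and by -0.64 (standard error 0.55) with the share of detected spots as a covariate, so that over 50% of it stayed but within 2 standard errors of 0; without GFP+ replicate 4, the array with the lowest naive level (-4.39) and share of detected spots (29.9%), it differed by -0.70 (exact permutation p = 0.0714), and p ran from 0.0159 to 0.111 over the 10 arrays left out in turn. A larger share of antigen-experienced cells among GFP+ cells is the biological explanation weighed, and the effector and memory genes had a median of 0.04, with members in both directions. The naive minus effector score differed by -1.10 (exact permutation p = 0.0159, adjusted 0.0476). Detection and cell state cannot be told apart here, because the difference with the covariate lies within 2 standard errors of 0 and the effector median decides nothing.

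Neutrophil RNA in the GFP- samples may underlie the low values of Ngp and S100a8 in GFP+ samples. With Ngp, S100a8 and S100a9 left out, 15 neutrophil genes, all above background on a GFP+ array and 6 shared with the fixed lists, had a median of -0.51, with 12 negative, which lies between the bounds set for and against this source. Of those brighter in GFP- samples, a choice that favours negative differences, Retnlg differed by -4.24, Mmp8 by -4.17 and Lcn2 by -2.27. Pglyrp1 differed by -1.98 and Ly6g by -0.53, while Csf3r, high in both groups, differed by -0.01. The positive ones were Cxcr2 (1.24), Lyz2 (0.85) and Hp (0.82). The source stays open, and S100a9 (1.44) and S100a8 (0.52) were abundant in GFP- samples, with no gate on myeloid cells given in the labels, while varying widely in GFP+ samples (SD 4.58 and 4.60).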
